A study of Acetivibrio thermocellus with 23 samples.

How the data were processed

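Total RNA of Clostridium thermocellum (now Acetivibrio thermocellus), an anaerobic bacterium that degrades cellulose, was measured on a single-colour Agilent array with Cy3-labelled cDNA. Per the labels, cultures of 10 mL grew at 60 °C with cellobiose at 2.2 g/L, in medium of pH 7.2, and RNA was taken at an optical density of about 0.37 (exponential phase) or about 0.80 (stationary phase, which another part of the labels calls late exponential). The 23 arrays form 4 groups: ATCC 27405 in exponential phase (n = 6), ATCC 27405 in stationary phase (n = 6), DSM 2650 in exponential phase (n = 6) and DSM 4150 in exponential phase (n = 5). The sample labels name the second strain DSM 2650, whereas the growth text gives the number 2360. The name of the sample labels is used here.

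Per the file headers, the arrays were read with Agilent Feature Extraction 10.10.1.1. The deposited array files hold the spot signal as intensity on a linear scale, after background subtraction and spatial detrending by that software. The same deposited files give the median spot and median background intensity and the background-subtracted intensity. The deposited files also hold other values, namely flags of 0 or 1 per spot for well above background, saturation and non-uniform or outlying spots. A separate table by the authors holds log2 values, 1 per probe, and its columns share 1 distribution with a median of 13.5, which is the form that quantile normalization between arrays gives. This was read from the values, since the tool behind the table is not given in the sources used here. Its values ranked the probes of an array as the processed spot intensities did, with Spearman correlations across probes from 0.996 to 1.000.

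The probe names carry a class prefix and a number. The files pair no probe with a gene name or a product, so the unit of every result is the probe. The array held 2976 probes of class 27405, 575 of class JW20, 387 of class 2360, 163 of class 64288 and 107 of class 64289, with 23 of class 64027 and 1 of class 64010. The classes were read from the prefix alone. The files place 383 class 2360 probes on contigs of strain 2360 and 4 on the ATCC 27405 chromosome. Class JW20 has 563 on JW20 contigs, 11 on 2360 contigs and 1 on that chromosome, and class 27405 has 2965 on the chromosome, 9 on 2360 contigs and 2 on JW20 contigs. ATCC 27405 gives the first class its name, and JW20 is another name of strain DSM 4150. What the prefixes 64288, 64289, 64027 and 64010 stand for is not given in the sources used here. A probe had 3 spots (3520 probes), 4 spots (412 probes) or 10 spots (300 probes).

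For each probe, the log2 of the processed intensity was averaged over the spots without an outlier or non-uniformity flag, and the 75th percentile of the array was subtracted. A probe was tested if more than 0.5 of its spots were well above background on all arrays, or all but 1, of at least 1 group. This left out 9 of 4232 probes as dim. A further 4 lacked unmarked spots on nearly all arrays of a group, so that 4219 probes were tested. The 4 groups were fitted together in limma 3.58.1 (R 4.3.3, lmFit and eBayes), with Benjamini-Hochberg adjusted p under 0.05 as the threshold and changes of at least 2-fold as a second count. Differences are in log2 units, and the p-values of limma are two-sided. Where a probe was not well above background on some array of the dimmer group, the fold is given as a lower bound. The bound divides the mean of the brighter group by that of the dimmer group after raising each dim value to the detection floor of its array, which is the lowest level on that array that still passed as well above background.

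Detection per class was compared as the percentage of measured probes well above background per array, with exact permutation tests over 20 comparisons. Classes were compared with Fisher's exact test over 40 comparisons, and runs of neighbouring probe numbers with 10000 shuffles of the class. Replicate spread was the median over probes of the absolute deviation of an array from the mean of the other arrays of its group, compared between groups by exact permutation. The number of replicates was studied for growth phase and for DSM 2650 against ATCC 27405, with 20 draws of arrays per size and with 20 divisions of each group into 3 and 3 arrays. The place of an ATCC 27405 array between the growth phases was its projection on the difference of the other stationary and other exponential arrays, where 0 is the exponential mean and 1 the stationary mean. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps.

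The comparisons, tests, filter, scaling, thresholds and most alternatives were chosen before the data were examined. The alternatives were other scalings, filters, variance models and thresholds, blocks for slide and replicate number, fits within slides, and leaving out 1 array at a time. Spike-in scaling, array row, the median-signal background correction, other detection rules, and the study of probe classes and probe numbers were chosen after seeing the data. The rule for named genes asked for the largest changes with an adjusted p under 0.05, no overlap between the arrays of the groups and an annotated product. Because the files do not pair probes with products, the rule was applied without the product, and 2 rises and 2 falls of each comparison are named by probe. Their rank is that of the fitted log2 difference, which in the strain comparisons includes values below the detection floor, so some unnamed probes have higher lower bounds than named ones. The gene lists chosen beforehand could not be run for the same reason. On simulated data with 50 changed probes per size, the fits recovered between 80% (both DSM 4150 comparisons) and 94% of changes of 1 log2 unit, and between 44% and 56% of changes of 0.5. False calls made up 4.40% to 7.82% of all calls, the most for DSM 4150 against DSM 2650. The simulation changed 200 probes and drew noise independently for each probe, with the same SD in all 4 groups. In the real groups the median SD ran from 0.146 (DSM 4150) to 0.304 (DSM 2650), and neighbouring probes changed together. The simulated rates therefore need not hold for the real calls.

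The median processed intensity per array ranged from 3592 to 15192, and the median of the negative controls from 2.88 to 28.6. Between 91.6% and 96.2% of probes were well above background, and 0 sample spots were saturated. The number of arrays limits the precision.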

Results

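The series is a pilot study whose design text asks how much replicate cultures of this bacterium vary and how many replicates give stable results. RNA of 3 strains was hybridised to an array with probes for several C. thermocellum genomes. Exponential cultures of ATCC 27405 (n = 6), DSM 2650 (n = 6) and DSM 4150 (n = 5) and stationary cultures of ATCC 27405 (n = 6) gave 23 arrays on 3 slides. Slide 1 held no DSM 4150 array. The median processed intensity per array ranged from 3592 to 15192 and exceeded that of the negative controls at least 319-fold on every array.

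Of classes 27405, 2360 and JW20, each strain gave signal at every measured probe of 1 class and lacked signal at a part of the probes of the other 2. Probes of class 27405 were well above background on 100% of measured probes in both ATCC 27405 groups (n = 6 and 6), against 94.2% ± 1.34 (SD, n = 6) in DSM 2650 and 94.7% ± 0.919 (SD, n = 5) in DSM 4150. Probes of class JW20, another name of DSM 4150, reached 100% in DSM 4150, 84.4% ± 1.59 (SD, n = 6) in exponential ATCC 27405 and 85.9% ± 2.86 (SD, n = 6) in DSM 2650. Probes of class 2360 reached 100% in DSM 2650, 84.6% ± 1.57 (SD, n = 6) in exponential ATCC 27405 and 85.3% ± 2.95 (SD, n = 5) in DSM 4150. Each of these differences between a strain and the others had an exact permutation p of 0.00217 (6 against 6 arrays) or 0.00433 (6 against 5), and an adjusted p of 0.00866 over 20 tests. The growth text names a strain 2360 where the sample labels say 2650. All 387 class 2360 probes gave signal in this strain, and 33 of them in no other strain. That argues against a strain that differs from 2360 at these probes as ATCC 27405 and DSM 4150 do. Another strain with the same sequences would give the same result, so which label is right stays open. Growth phase left the share of class 27405 at 100%, the highest it can be. In stationary ATCC 27405 the shares of classes JW20 and 2360 were 86.2% and 86.0% (exact permutation p = 0.184 and 0.338 against exponential). Class 64288 reached 99.8% ± 0.336 (SD, n = 5) in DSM 4150 and 93.9% ± 0.639 (SD, n = 6) in exponential ATCC 27405, a difference with an exact permutation p of 0.00433 (adjusted p = 0.00866).

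**Figure D1:**
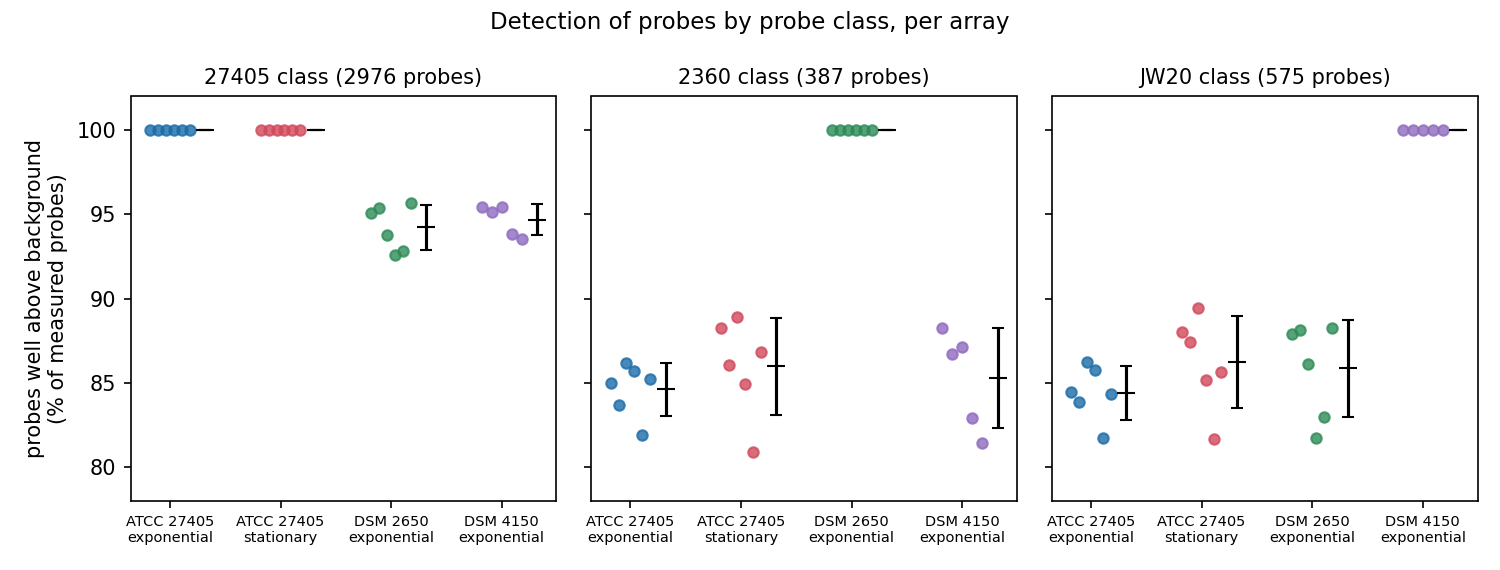
Share of the measured probes of 3 probe classes that were well above background (%, axis from 78), with 1 point per array and the mean ± SD of each group as bars. Class 27405 sits at 100% in both ATCC 27405 groups, class 2360 in DSM 2650 and class JW20 in DSM 4150, and each lies between 80.9% and 95.7% elsewhere.

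The strains shared most of their missing probes. Of 2976 class 27405 probes, 119 were not well above background on any DSM 2650 array, 126 on any DSM 4150 array, and 97 on any array of either strain, where 5.04 would be shared by chance (odds ratio 430, two-sided Fisher's exact p = 6.16e-133). In exponential ATCC 27405 the 119 and 126 probes exceeded the detection floor of the other strain by a median of at least 208-fold and at least 206-fold. A further 47 of 387 class 2360 probes and 72 of 575 class JW20 probes lacked signal on every exponential ATCC 27405 array. In DSM 4150, 42 class 2360 probes lacked signal, as did 61 class JW20 probes in DSM 2650. The missing class 27405 probes lay beside each other in the probe numbering. The Fisher's exact test above treats probes as independent, so its p overstates the certainty. Those missing in DSM 2650 formed 51 neighbouring pairs, against a mean of 4.72 in 10000 shuffles, and those missing in DSM 4150 formed 67, against 5.32 (permutation p = 0.0001 for each, the smallest the shuffles can give). The longest run held 8 probes in each strain. Under the looser flag of a positive and significant signal, 38 and 68 class 27405 probes lacked signal in DSM 2650 and DSM 4150, and 22 class 2360 and 22 class JW20 probes in exponential ATCC 27405.

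The comparison of growth phases asked what changed in ATCC 27405 between exponential and stationary cultures. Large changes were mostly falls. Falls were more frequent in class 27405 than in all other classes pooled, and those of class 27405 had neighbouring numbers more often than in shuffles. Rises of at least 2-fold were not more frequent in class 27405 (0.471% of its probes against 1.21% of all others). Of 4219 probes tested, 248 changed at least 2-fold, 29 of them higher and 219 lower in stationary cultures (limma, n = 6 and 6). The rises numbered 9 with centring on the median and 101 with quantile normalization, beside 285 and 320 falls. Falls of at least 2-fold made up 6.25% of class 27405 probes (186 of 2975) and 2.65% of all others (two-sided Fisher's exact test, adjusted p = 1.55e-06 over 40 tests), and class JW20 had 8 rises and 11 falls of that size (26 and 13 without stationary replicates 6 and 12, an alternative chosen after seeing the data). The pooled share hides class 64289, where falls of at least 2-fold made up 8% (8 of 100). That compares with 5.12% of all probes outside class 64289 (two-sided Fisher's exact test, adjusted p = 0.29). The higher share of falls in class 27405 than in all others pooled held, at an unadjusted p under 0.05, under 5 other scalings or background corrections. These tests are across probes, which are not independent replicates.

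A run of 31 class 27405 probes, numbers 2775 to 2806, fell together by a median of 1.82 log2 units in stationary cultures. The run was picked as the longest unbroken stretch of class 27405 probes called lower by at least 2-fold in this same fit. That each of the 31 probes was called lower therefore follows from the choice. Their adjusted p was at most 0.000317 (limma). Under 5 other scalings or background corrections of the same arrays each was called lower as well. Their adjusted p was then at most 0.000663 (limma), with medians from -1.98 to -1.76. The 186 probes with falls of at least 2-fold formed 105 neighbouring pairs, against a mean of 11.6 and a maximum of 28 in the shuffles (permutation p = 0.0001, the smallest they can give), and the next longest run held 10 probes. Runs of at least 5 probes held 34.4% of the 186. Among class 27405 probes well above background on every array of both groups, the changes of neighbours correlated across 2794 pairs. The Spearman rho was 0.63 (permutation p = 0.0005, the smallest that the shuffles can give). Over all tested class 27405 probes, rho was 0.62 across 2860 pairs. The differences of DSM 2650 and DSM 4150 from ATCC 27405 also correlated between neighbours, with a rho of 0.57 and 0.55. These values leave out probes that were not well above background on some array of the strains compared.

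The files do not pair these probes with genes, and they place probe JW20_4696 on a contig of strain 2360. Among probes without overlap between the arrays of the groups, the largest rises were those of probes JW20_4696 and 27405_1994. Probe JW20_4696 went from 0.15 ± 0.21 to 2.24 ± 0.87 log2 units relative to the 75th percentile of the array (mean ± SD, n = 6 and 6). Probe 27405_1994 went from 1.06 ± 0.08 to 2.63 ± 0.88. Probe JW20_4696 was 4.26-fold higher (log2 difference 2.09, SE 0.28, adjusted p = 2.22e-05 by limma), and probe 27405_1994 was 2.98-fold higher (1.57, SE 0.26, adjusted p = 0.000110). The largest falls among such probes were those of probe 27405_0419, from 2.60 ± 0.19 to -0.09 ± 1.37, and probe 27405_0337, from 2.82 ± 0.23 to 0.19 ± 1.57. Probe 27405_0419 changed by -2.69 log2 units (SE 0.42, adjusted p = 7.22e-05 by limma) and probe 27405_0337 by -2.63 (SE 0.47, adjusted p = 0.000227). The lack of overlap was part of the rule that picked these 4 probes, so it is no further evidence. Of 4219 tested probes, 810 had no overlap. Larger changes among overlapping probes, if any, are not named.

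**Figure D2:**
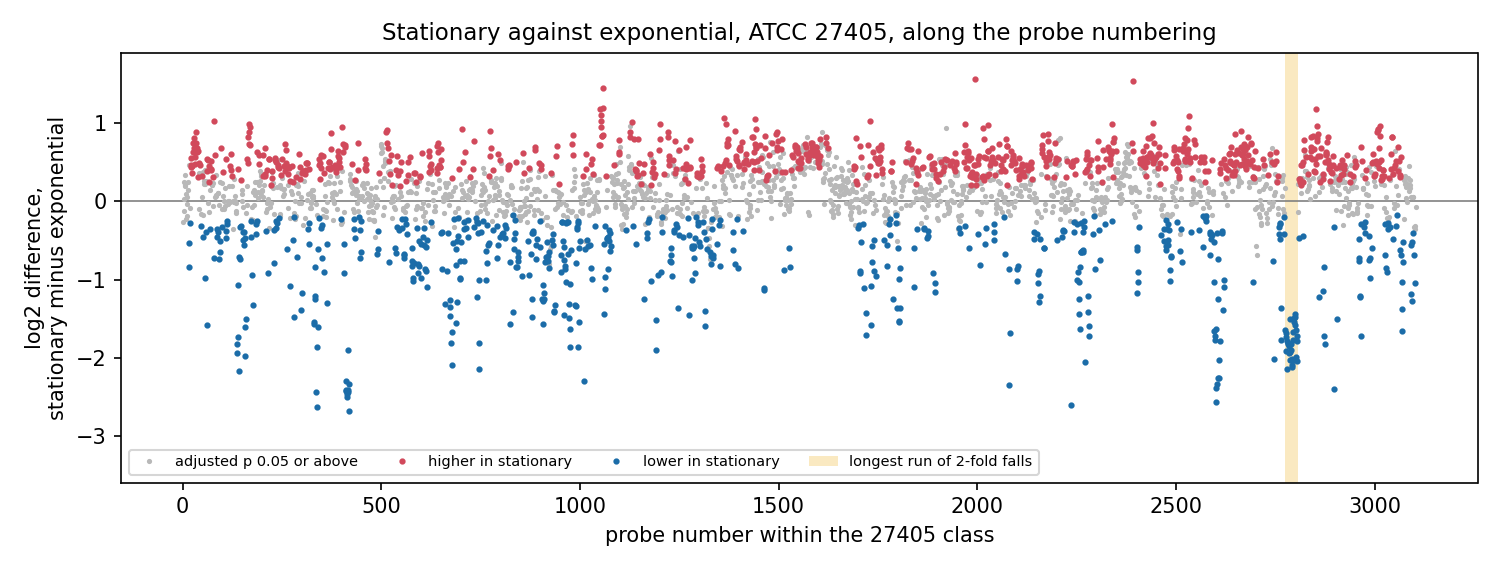
Difference between stationary and exponential ATCC 27405 (log2 units) for each class 27405 probe against its probe number, with probes of adjusted p under 0.05 in colour. The shaded band marks the run of 31 probes with falls of at least 2-fold, at numbers 2775 to 2806.

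By number, 1971 of 4219 probes passed the threshold, 1195 higher and 776 lower. The split into higher and lower depended on the scaling: the median of all probes was 0.17 log2 units, centring on the median shifted it by -0.17 and gave 821 higher and 1025 lower, and scaling to the spike-in probes, which shifted it by only -0.01, gave 44 higher and 399 lower out of fewer calls. Within slides, the count was 1299 on slide 1 (3 exponential and 2 stationary arrays), 1 on slide 2 (2 and 1) and 0 on slide 3 (1 and 3), where limma gave 609 and 509 probes at an unadjusted p under 0.05. Within array row 1 (1 and 4) it was 5, with 729 at an unadjusted p under 0.05, and within array row 2 (5 and 2) it was 1970. The 4 named probes kept their direction but not their calls on slide 2, slide 3 and array row 1. With slide as a block the count was 2057, and with array row as a block 2371.

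The 6 stationary cultures lay at unequal distances from the exponential ones. On the axis from the exponential mean (0) to the stationary mean (1), stationary replicates 3, 4, 9 and 11 lay at 1.47, 1.32, 1.25 and 0.987, replicate 6 at 0.583 and replicate 12 at 0.205. The exponential arrays lay between 0.0484 and 0.179, apart from replicate 4 at -0.351. Without stationary replicates 6 and 12, 2381 probes passed the threshold, 1589 higher and 792 lower, and 143 rose and 296 fell at least 2-fold. The 31 probes of the run then fell by a median of 2.37 log2 units.

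**Figure D3:**
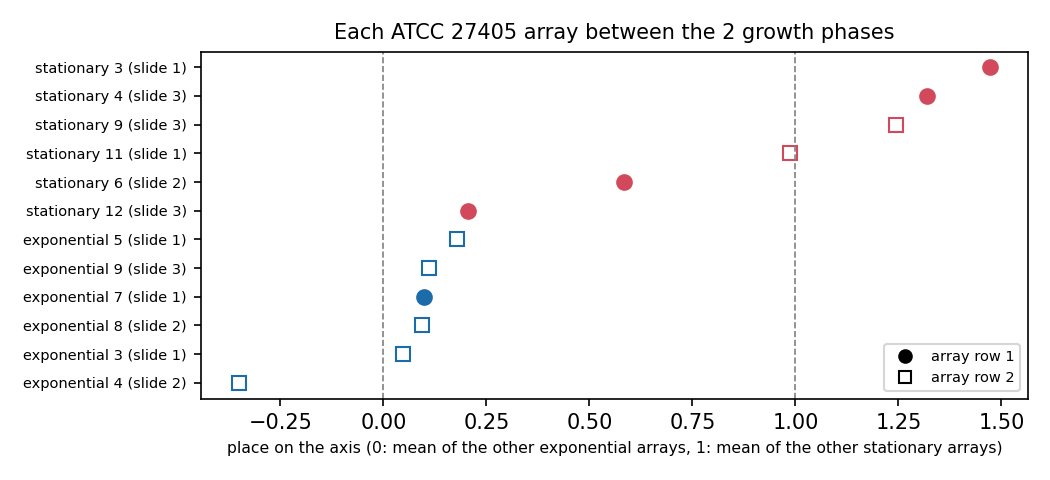
Place of each ATCC 27405 array between the exponential mean (0) and the stationary mean (1) of the other arrays, in units of that difference, with filled circles for array row 1 and open squares for array row 2. Stationary replicate 12 sits at 0.205, next to exponential replicate 5 at 0.179.

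The comparison of DSM 2650 with ATCC 27405 in exponential phase asked how the strains differ in the same growth phase. Class 2360 probes were the ones most often higher in DSM 2650: 113 of 386 rose at least 2-fold (29.3%, against 6.29% of other probes, Fisher's exact adjusted p = 5.90e-37). Class 27405 probes were more often lower by that amount, 441 of 2975 (14.8%, against 7.96%, adjusted p = 9.27e-10). Part of these counts comes from probes without signal in 1 strain. A probe with signal in both strains may still match their sequences unequally, which was not tested. Differences at such probes, here and in the other strain comparisons, may thus reflect sequence as well as RNA level. Among the probes well above background on every array of both strains, 39 of 301 class 2360 probes were at least 2-fold higher (13% against 6.13%, adjusted p = 0.00013), whereas class 27405 was no longer lower more often (212 of 2737, 7.75% against 7.08%, adjusted p = 0.601). Of all class JW20 probes, 69 were higher and 67 lower, a balance that turned with the scaling (163 and 54 with quantile normalization, 44 and 176 with spike-in scaling). Over all tested probes, the 2 class tests passed an unadjusted p of 0.05 in the same direction under 5 other scalings or background corrections. Probe 64289_0735 was at least 620-fold higher in DSM 2650 (0.63 ± 0.31 log2 units, SD, n = 6, adjusted p = 4.40e-17 by limma) and probe 2360_5570 at least 589-fold higher (0.56 ± 0.23, adjusted p = 2.23e-14), each with signal on none of the 6 ATCC 27405 arrays. Probe 27405_2722 was at least 879-fold lower in DSM 2650 (0.80 ± 0.22 in ATCC 27405, n = 6, adjusted p = 3.08e-17 by limma) and probe 27405_2091 at least 760-fold lower (0.59 ± 0.13, adjusted p = 7.69e-16), each with signal on none of the 6 DSM 2650 arrays.

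In all, 2080 of 4219 probes differed between DSM 2650 and ATCC 27405, 801 higher and 1279 lower, and 894 at least 2-fold (354 higher, 540 lower). Among the 3712 probes well above background on every array of both strains, 1698 differed (687 higher, 1011 lower), 529 of them at least 2-fold (248 higher, 281 lower). The split again depended on the scaling: centring on the median shifted the median of all probes by 0.12 log2 units and gave 1019 higher and 1058 lower, quantile normalization shifted it by 0.17 and gave 1290 higher and 1005 lower, and scaling to the spike-in probes shifted it by -0.68 and gave 287 higher and 2932 lower. At 2-fold, quantile normalization gave 552 higher and 466 lower, and spike-in scaling 209 and 1350. Within slides 1, 2 and 3 the counts were 1232, 1361 and 1216, and within array rows 1 and 2 they were 1371 and 1696.

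**Figure D4:**
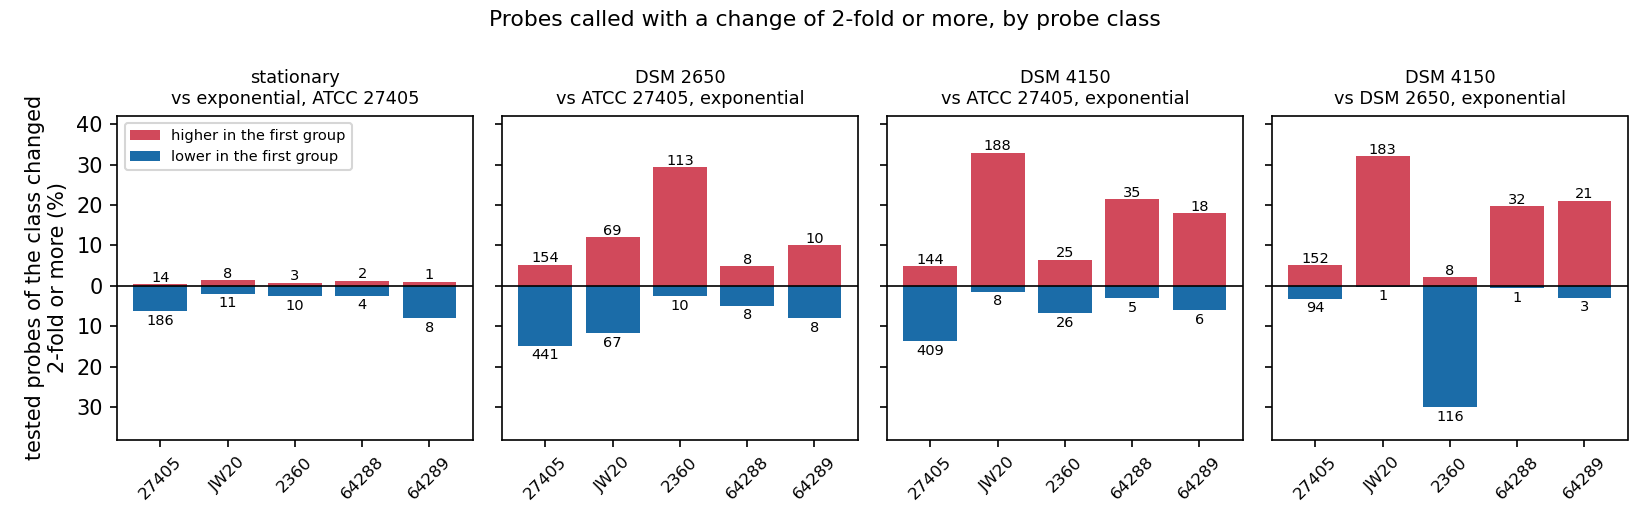
Percentage of the tested probes of 5 classes that were called with a change of at least 2-fold, higher above 0 and lower below 0, with the number of probes at each bar, for the 4 comparisons. In the strain comparisons, 113 class 2360 probes were higher in DSM 2650 and 188 class JW20 probes higher in DSM 4150 than in ATCC 27405.

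The comparison of DSM 4150 with ATCC 27405 in exponential phase put the same question for the third strain. Class JW20 probes were most often higher in DSM 4150, with 188 of 571 at least 2-fold higher (32.9%, against 6.11% of other probes, Fisher's exact adjusted p = 3.05e-64). Class 27405 probes were more often lower, 409 of 2975 (13.7%, against 4.10%, adjusted p = 2.76e-22), and both class tests kept their direction, at an unadjusted p under 0.05, under 5 other scalings or background corrections. Both were smaller among the probes well above background on every array of both strains, where 78 of 444 class JW20 probes were higher (17.6% against 5.75%, adjusted p = 2.47e-14) and 203 of 2753 class 27405 probes lower (7.37% against 3.62%, adjusted p = 6.45e-05). As for DSM 2650, such differences may reflect sequence as well as RNA level. Of all tested probes, classes 64288 and 64289 had 35 and 18 probes at least 2-fold higher. Probe 64289_0735 was at least 653-fold higher (0.71 ± 0.27 log2 units, SD, n = 5, adjusted p = 1.27e-16 by limma), as it was in DSM 2650, and probe 64289_0579 at least 436-fold higher (0.12 ± 0.18, adjusted p = 1.04e-16). Probe 27405_3101 was at least 1156-fold lower (1.18 ± 0.11 in ATCC 27405, n = 6, adjusted p = 9.13e-17 by limma) and probe 27405_1922 at least 859-fold lower (0.75 ± 0.10, adjusted p = 2.33e-16). The dimmer strain gave no signal for these 4 probes on any array.

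In all, 1977 of 4219 probes differed between DSM 4150 and ATCC 27405, 836 higher and 1141 lower, and 871 at least 2-fold (411 higher, 460 lower). Among the 3748 probes well above background on every array of both strains, 1607 differed (690 higher, 917 lower), 507 at least 2-fold (268 higher, 239 lower). Scaling to the spike-in probes shifted the median of all probes by -0.30 log2 units and gave 419 higher and 1150 lower. At 2-fold, quantile normalization gave 543 higher and 436 lower. Within slides 2 and 3 the counts were 1465 and 955, and within array rows 1 and 2 they were 1108 and 1602.

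The direct comparison of DSM 4150 with DSM 2650 asked how these strains differ from each other. Here too, differences at probes with signal in both strains may reflect sequence as well as RNA level. Class JW20 probes were most often higher in DSM 4150 (183 of 571 at least 2-fold, 32% against 5.95%, Fisher's exact adjusted p = 1.88e-62) and class 2360 probes most often lower (116 of 386, 30.1% against 2.64%, adjusted p = 1.82e-66), in the same direction at an unadjusted p under 0.05 under 5 other scalings or background corrections. Among the probes well above background on every array of both strains, 76 of 455 class JW20 probes were higher (16.7% against 4.55%, adjusted p = 5.17e-17) and 38 of 300 class 2360 probes lower (12.7% against 2.3%, adjusted p = 7.36e-14). Probe 64288_7767 was at least 1294-fold higher in DSM 4150 (1.44 ± 0.27 log2 units, SD, n = 5, adjusted p = 4.85e-19 by limma) and probe 27405_2722 at least 1236-fold higher (1.29 ± 0.36, adjusted p = 4.05e-17), with signal on none of the 6 DSM 2650 arrays. Probe 27405_1513 was at least 2046-fold lower in DSM 4150 (2.91 ± 0.47 in DSM 2650, n = 6, adjusted p = 1.67e-18 by limma) and its neighbour 27405_1512 at least 1407-fold lower (1.79 ± 0.35, adjusted p = 1.72e-20). These probes were well above background on 3 and 1 of the 5 DSM 4150 arrays.

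Of 4219 probes, 1440 differed between DSM 4150 and DSM 2650, 755 higher and 685 lower, and 617 at least 2-fold (400 higher, 217 lower). Of the 3732 probes well above background on every array of both strains, 1160 differed (579 higher, 581 lower), 342 at least 2-fold (225 higher, 117 lower). Quantile normalization shifted the median of all probes by -0.12 log2 units and gave 669 higher and 1023 lower, centring on the median shifted it by -0.11, the log2 table of the authors gave 679 higher and 1005 lower, and scaling to the spike-in probes shifted it by 0.37 and gave 767 higher and 216 lower. At 2-fold, quantile normalization gave 340 higher and 342 lower. Within slides 2 and 3 the counts were 828 and 1184, and within array rows 1 and 2 they were 1634 and 809.

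The differences of DSM 2650 and of DSM 4150 from ATCC 27405 overlapped beyond what noise in their shared control arrays gives. Of the probes called in both comparisons, 474 were higher in both strains (158.7 by chance), 817 lower in both (345.9 by chance) and 98 in opposite directions. With quantile normalization, 839 were higher in both (334.8 by chance) and 697 lower in both (264.2 by chance). Across probes, the differences correlated with a Pearson r of 0.62 and a Spearman rho of 0.573, where simulated unchanged groups with the same shared controls gave an r of 0.476. Their covariance was 4.28, against 0.0230 in the simulated groups. With the 6 control arrays divided so that each strain had its own 3, r was 0.623 on average over 20 divisions, and among the 3672 probes well above background on every array of the 3 groups it was 0.640 with a covariance of 0.634. Probes are not independent replicates, so no p is given. Dividing the control arrays and simulating unchanged groups address array noise only, since both differences still subtract the same strain, ATCC 27405. A probe at which ATCC 27405 alone differs would appear in both. The overlap therefore cannot show a change shared by the DSM strains.

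No difference in replicate spread between groups passed the threshold after adjustment. The median absolute deviation of an array from its group was 0.139 ± 0.0627 log2 units (SD, n = 6) in exponential ATCC 27405, 0.239 ± 0.0804 (n = 6) in stationary ATCC 27405, 0.275 ± 0.163 (n = 6) in DSM 2650 and 0.133 ± 0.0181 (n = 5) in DSM 4150. Stationary ATCC 27405 against DSM 4150 had an exact permutation p of 0.00866 (adjusted p = 0.0519 over 6 tests), and stationary against exponential ATCC 27405 an exact permutation p of 0.0368 (adjusted p = 0.110). After quantile normalization, stationary ATCC 27405 exceeded DSM 4150 by 0.129 and DSM 2650 by 0.109, where the difference from DSM 2650 was -0.0366 before, and exponential minus stationary ATCC 27405 was -0.130. These 3 differences then passed the threshold (exact permutation adjusted p = 0.00866 for each). The spots of a probe accounted for 25.1% of the variance between exponential ATCC 27405 arrays and 24.3% in DSM 4150, against 6.69% in stationary ATCC 27405 and 4.62% in DSM 2650.

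Draws of fewer arrays recovered on average a smaller share of the calls for growth phase than for DSM 2650 against ATCC 27405, the 2 comparisons for which they were run. For growth phase, draws of 2, 3, 4 and 5 arrays per group recovered on average 18.6%, 38.2%, 58.3% and 84.6% of the 2189 probes called with the 6 and 6 arrays alone, and single draws of 3 arrays recovered between 0% and 89.8%. For DSM 2650 against ATCC 27405, the same draws recovered 53.4%, 68.4%, 82.0% and 90.3% of 2021 probes, and for changes of at least 2-fold 85.4%, 93.3%, 95.5% and 97.5%. Changes of at least 2-fold between growth phases were recovered at 29.2%, 50.8%, 76.5% and 93.1%, with single draws of 3 arrays between 0% and 98.8%. The draws used all tested probes, including those without signal in 1 strain. In the fit of all 4 groups, 529 of 894 changes of at least 2-fold in DSM 2650 were at probes well above background on every array. For growth phase these were 237 of 248. The 2 comparisons are thus not like for like, and recovery among such probes alone was not computed. Draws share arrays with the full set, whereas groups of 6 divided into sets of 3 and 3 arrays do not. All 20 sets of 3 with stationary replicate 12 gave at most 1 call in limma (19 gave 0, with a median of 966 probes at an unadjusted p under 0.05), and the 20 without it gave between 938 and 2569. The sets without replicate 12 therefore shared 0% of their calls with the opposite set, although at the median 98.5% of their called probes had the same sign there. Sets of 3 arrays of DSM 2650 and ATCC 27405 gave a median of 1380 calls, of which 79.2% were called in the opposite set.

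**Figure D5:**
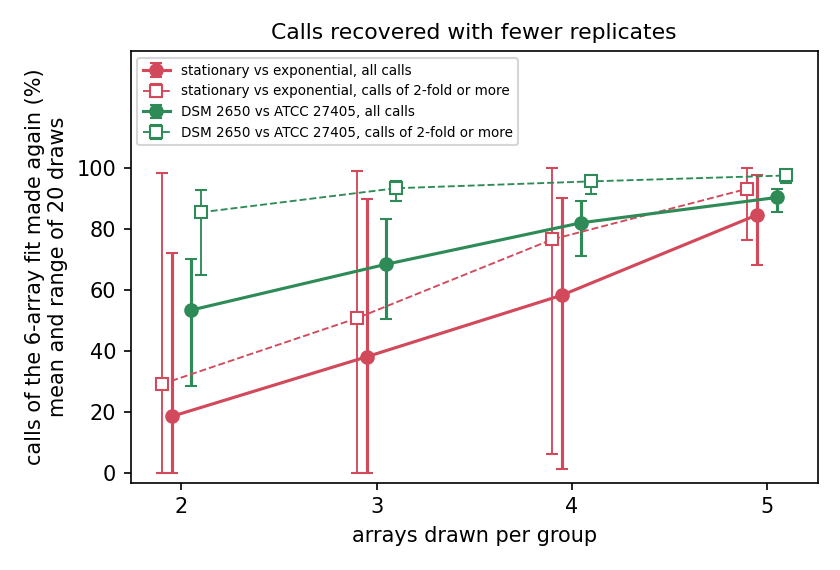
Percentage of the probes called with 6 arrays per group that were called again with 2 to 5 arrays per group, as the mean (points) and range (bars) of 20 draws. For DSM 2650 against ATCC 27405, changes of at least 2-fold were recovered at 85.4% with 2 arrays, against 29.2% for growth phase.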

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

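The tests of explanations and of other divisions of the arrays in this part were chosen only after the result was seen, except those of spot position and of a trend along the numbering. Arrays were compared within their groups on 7 measures, in 26 tests, where chance alone gives about 1.3 such values, and 4 values, from 3 arrays, stood apart.

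The median negative-control signal of DSM 4150 replicate 8 was 28.55, and the next array of the group had 10.3. The median absolute deviation from the other arrays was 0.2641 log2 units for exponential ATCC 27405 replicate 4, where the next array had 0.134. On the axis between the growth phases, the same array lay at -0.351, below the next array at 0.0484. Without it, 1577 probes differed between the growth phases. The median absolute deviation of stationary ATCC 27405 replicate 12 was 0.3909 log2 units, where the next array had 0.232.

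Stationary replicate 12 lay at 0.205 on the axis between the growth phases, near the exponential arrays, and sets of 3 stationary arrays that held it gave at most 1 call. Slide and array row as the cause were argued against by stationary replicate 4, from the same slide and array row, at 1.32. A swap with an exponential array was argued against because the highest exponential array lay at 0.179. An exponential culture under a stationary label stays open but undecided, since the deviation of replicate 12 from the exponential mean was 0.641 times that of exponential replicate 4, which itself stands apart, and 1.26 times that of the next exponential array. A culture sampled between the phases may be the source. The difference of replicate 12 from exponential arrays correlated across probes with that of the other stationary arrays at 0.379. Exponential arrays put in its place gave values from -0.564 (replicate 4) to 0.2645. The lowest of these was larger in size than 0.379, so 1 value above the highest is weak ground for this source.

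Of the class 27405 probes, 119 and 126 gave no signal in DSM 2650 and DSM 4150. Arrays too dim to show weak probes were argued against, since the missing probe nearest to the detection floor was still 35.7-fold above it in ATCC 27405, although 29.1% of the 148 probes missing in either strain were among the dimmest 10% of the class, so that an earlier form of this test decided nothing. Random silencing of genes that the strains carry was argued against by 0 of 962 probes of class 2360 in DSM 2650 and class JW20 in DSM 4150 without signal, where 39.6 were predicted (binomial p = 2.7e-18; class JW20 alone, 0 of 575 with 23.7 predicted, p = 3.19e-11; only probes placed on contigs of the strain of their class, 0 of 946 with 38.9 predicted, p = 5.38e-18), unless the design had kept only probes that hybridised with RNA of their own strain, which is not given in the sources used here. A sequence absent from or different in the strain may be the source, since 0 of 3938 probes of class 27405 in ATCC 27405, class JW20 in DSM 4150 and class 2360 in DSM 2650 lacked signal, or 0 of 3551 without class 2360, whose strain number differs from the label. The binomial test treats probes as independent, whereas missing class 27405 probes lay beside each other, so its p overstates the certainty. The 0 of 3938 would also be seen if the design had kept only probes that hybridised with RNA of their own strain. In that case it would be no evidence about sequence. The strains' genomes were not used here.

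Class 27405 probes with neighbouring numbers changed together in stationary phase, and so did their differences between strains (Spearman rho across probes 0.63 for growth phase, 0.57 for DSM 2650 and 0.55 for DSM 4150 against ATCC 27405). These values are from probes well above background on every array of the groups compared. The position of the spots was argued against by a correlation of -0.006 between the changes of adjoining spots (Spearman, across 44819 pairs), and a slow trend along the numbering by a correlation of 0.10 at a distance of 20 numbers. Groups of adjacent genes regulated together, such as operons, may be the source, since the correlation at a distance of 1 exceeded that at 20 by 0.52. The files used give no positions, so whether the probe numbers follow the order of genes was not tested. Whether sequence differences add to the correlations of the strain differences was not tested either.

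Other divisions of the arrays into groups of the same sizes were counted for each comparison. For each of the 4 comparisons, 1 of 100 divisions drawn from 462, the real one, gave as many calls. That argues against chance but cannot exclude it. A share of 1 in 100 is the smallest these draws can give, and they ignored slide and array row. The real counts were 1971 for growth phase, 2080 and 1977 for DSM 2650 and DSM 4150 against ATCC 27405 and 1440 for DSM 4150 against DSM 2650. The highest counts of the other divisions were 1097, 1487, 1651 and 1093.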

How the results depend on the processing

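Array row, spike-in scaling, the median-signal background correction, marked spots kept, fits on probes well above background on every array, and the detection rules were chosen only after the result was seen. Under alternatives, 116 counts of calls stayed within 1.5 times the count reported and 17 did not. Leaving out 1 array at a time gave 1577 to 2234 calls for growth phase, 1956 to 2191 for DSM 2650 against ATCC 27405, 1808 to 1936 for DSM 4150 against ATCC 27405 and 1290 to 1518 for DSM 4150 against DSM 2650. For growth phase, the count moved to 1221 at an adjusted p under 0.01, 443 with spike-in scaling, 1299, 1 and 0 within slides 1, 2 and 3 and 5 within array row 1. Limma gave 609 and 509 probes at an unadjusted p under 0.05 within slides 2 and 3, and a group with 1 array on a slide was taken to vary like the others. For DSM 2650 against ATCC 27405 it moved to 3219 with spike-in scaling, 1232, 1361 and 1216 within slides 1, 2 and 3 and 1371 within array row 1. For DSM 4150 against ATCC 27405 it moved to 955 within slide 3 and 1108 within array row 1, and for DSM 4150 against DSM 2650 to 828 within slide 2 and 809 within array row 2. Fits within a slide or array row use fewer arrays. Of the stationary arrays, slide 1 held replicates 3 and 11, and array row 2 held 9 and 11. Slide 2 held only replicate 6, and slide 3 and array row 1 held replicate 12. The low growth phase counts thus coincide with the stationary replicates nearest the exponential arrays. They also coincide with groups of 1 array, and these cannot be told apart here. The cause was not tested for the rest.

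With the replicate number as a block, in fits of the compared groups alone, the counts were 2638 for growth phase, 1398 for DSM 2650 against ATCC 27405, 1023 for DSM 4150 against ATCC 27405 and 595 for DSM 4150 against DSM 2650. Without the block, fits of the compared groups alone gave 2189 for growth phase and 2021 for DSM 2650 against ATCC 27405. The counts from the fit of all 4 groups are not a like-for-like reference. The labels do not say that equal numbers pair cultures, so numbers were not used as pairs. After removing group means, arrays with the same number correlated across probes at -0.47 to 0.28 for growth phase and -0.07 to -0.02 for DSM 2650 against ATCC 27405. For DSM 4150, the 2 shared numbers gave 0.13 and 0.13 against ATCC 27405, each its own best match, and 0.03 and 0.23 against DSM 2650, 1 of them its own best match. With 2 pairs each, pairing stays undecided there. The cause was not tested.

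For named probes, 492 values kept their direction and call, 12 kept their direction only, and 0 reversed. The 12 were the 4 probes of the growth phase comparison within slides 2 and 3 and array row 1, with adjusted p from 0.131 to 0.657. With quantile normalization, differences in replicate spread were -0.130 (exponential minus stationary ATCC 27405), 0.109 (stationary ATCC 27405 minus DSM 2650, reversed from -0.0366) and 0.129 (stationary ATCC 27405 minus DSM 4150). The cause was not tested. Among probes well above background on every array of both strains, class 27405 was not lower more often in DSM 2650 (7.75% against 7.08%, Fisher's exact adjusted p = 0.601), and the other class differences reported kept their direction. Changes of at least 2-fold in DSM 2650, including probes without signal in 1 strain, were recovered at 85.4%, 93.3%, 95.5% and 97.5% with 2, 3, 4 and 5 arrays. Those between growth phases were recovered at 29.2%, 50.8%, 76.5% and 93.1%. With the positive and significant flag, 38 and 68 class 27405 probes lacked signal in DSM 2650 and DSM 4150, and 22 class 2360 and 22 class JW20 probes in exponential ATCC 27405. That rule accepts weaker signals by its construction. The number of probes that differed from ATCC 27405 in the same direction in both DSM strains stayed within 1.5 times, from 1038 to 1536. With quantile normalization, however, those higher in both strains moved from 474 to 839. Gene lists, the median over probes of a gene, the brightest probe of a gene, and background correction on the mean spot signal were not run, since no gene names or mean signals were in the files used.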

Other observations

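The groupings in this part were chosen only after the result was seen. Across all classes, 3750 of 4232 probes were well above background on every exponential array of the 3 strains. Only ATCC 27405 gave signal on all its arrays, and the other strains on none, for 97 probes, all of class 27405. For 33 probes this held for DSM 2650 alone, all of class 2360, and for 55 probes for DSM 4150 alone, of which 47 were of class JW20, 6 of class 64288 and 2 of class 64289. Both DSM strains gave signal and ATCC 27405 none for 26 probes. Of these, 18 were of class JW20, 5 of class 2360, 2 of class 64289 and 1 of class 64288. A further 5 probes, all of class 64289, gave signal on no array of the 3 groups, and 219 probes gave signal on some arrays of a strain only.

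The class 27405 probes called higher in stationary cultures also had neighbouring numbers, with 480 pairs among 853 probes, against a mean of 244 in the shuffles (permutation p = 0.0001, the smallest they can give).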
